A study of Mus musculus with 7 samples.

How the data were processed

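Bulk RNA sequencing libraries were made by the submitters from muscle endothelial cells of mice, 3 labelled wild type and 4 labelled endothelial GLUT1 knockout. Per the labels, cells were isolated with beads, RNA was extracted at once with an RNeasy Plus kit, and 10 ng of RNA went into libraries built with a Takara Clontech PicoMammalian v2 kit. All sample descriptions carry 1 date, so the labels give no batch, and the meaning of the code HO in the descriptions of the knockout group is not given in the sources used here. Groups and replicate numbers come from the sample titles.

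The values used are the authors' normalised counts per gene, a scaled expression signal with 1 deposited table per library. The submitters' processing notes name kallisto, featureCounts, DESeq, DESeq2 and the genome build GRCm39, with no role or version for the tools. The deposited values were not whole and their totals differed between libraries. Low values gathered near multiples of a step in each library, but 24.6% to 49.6% of the values in the first 10 steps lay within 0.02 steps of a whole multiple, so whole reads were not recovered. Tests that need whole reads, edgeR and DESeq2, were therefore not run. The step, the smallest value repeated exactly at least 20 times, gave the estimate of reads per library, 11260176 to 18020310, which limits the precision of low values. No counting interval is given, since whole reads were not recovered.

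Genes are named by symbol as in the tables. Biotypes and exonic lengths were looked up by symbol in a mouse annotation of an older build than the submitters', which matched 29784 symbols (96.4%) and gave a length to 97.6% of the tested genes. No coordinates are given for that reason. Some symbols share reads with close paralogues, among them Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, and Rn7s1 and Rn7s2, and whether strands were kept apart in counting is not given in the sources used here, which bears on antisense transcripts such as Kdm6bos.

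Values were analysed as log2 of the normalised count plus 1, which shrinks fold changes of genes near 0. Genes with a mean of at least 10 over the 7 libraries were tested, 16931 of 30899, with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Changes are the knockout label minus wild type. Intervals are 95% intervals from the same model. Single values, such as shares per library, were compared with a two-sided exact permutation test over the 35 splits of the 7 libraries, whose smallest p is 0.0286, adjusted over 9 library measures.

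Gene lists for metabolism, stress, endothelial subtypes, signalling and other cell types, 45 in all, were fixed before the data were examined, as were the main test, the rule for named genes and the first set of alternatives. The 43 lists with at least 3 tested members were compared with all other genes by limma camera with a preset correlation of 0.01, adjusted over the lists. Camera was repeated with an estimated correlation, and fry tested whether a list's genes moved on balance one way. After the data were seen, list medians were also set against 10000 random lists matched on mean expression, drawn from 100 genes on each side, and against 10000 lists matched within 0.75 log2 units of mean and 0.25 log2 units of exonic length among protein-coding genes with a mean of at least 100. Comparisons on length used only list members within those limits and with enough matches. That left 4 of 8 satellite cell, 3 of 5 erythroid, 3 of 5 tenocyte, 8 of 14 fibroadipogenic progenitor and 9 of 25 proliferation genes. Calls on mean and length thus cover part of some lists.

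The genes named are Slc2a1; among changed genes with an ordinary symbol, a mean of at least 50 and no overlap between groups (933 higher and 354 lower), the 8 largest changes and then the 5 smallest p in each direction; up to 4 changed members of each list with the smallest p, or up to 2 values where none changed; 13 genes fixed in advance, Spp1, Csf1, Cd36, Txnip, Hk1, Hk2, Pfkfb3, Slc2a3, Slc16a1, Pecam1, Cdh5, Kdr and Nos3; and the 3 most abundant members of other-cell lists that differed. Not every gene so named is given with its values, and some are not reported here.

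The alternatives chosen then were a pseudocount of 0.5 or 5, no filter on low values or a mean of at least 50, quantile normalization, equal totals, median ratios, limma without trend, robust limma, array weights, the replicate number as a block, covariates for muscle fibre and macrophage markers, an adjusted p of 0.10, and leaving out each library. Alternatives added after the data were seen were the receptor genes' mean log2 value as a covariate, subtraction of the receptor level per kilobase of exon, removal of a trend on exonic length over all genes or over expressed genes (loess, span 0.5), and the matched random lists. On simulated data with 200 changed genes among 16931, over 20 runs, the main test recovered 27.2% of 1.5-fold, 79.3% of 2-fold and 99.3% of 4-fold changes, with 6.36% of calls false. The changed genes were drawn from those with a mean of at least 100, and the noise was independent between genes. That noise was normal, with each gene's spread taken from the main fit itself, so the simulation had the mean-variance trend built in. It therefore cannot test that trend or the count of changed genes in the real data. Limma without trend made 77 calls per simulated run, against 146 with it. Recovery under that mean, and the rates where genes vary together, were not measured. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with pandas 2.3.3.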

Results

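Gene expression was measured by bulk RNA sequencing in endothelial cells isolated with beads from mouse skeletal muscle, with RNA taken directly after isolation. The libraries fell into 2 groups by genotype, 3 from wild-type mice and 4 from mice labelled as lacking GLUT1 in the endothelium. GLUT1, the facilitative glucose transporter encoded by Slc2a1, is the main glucose carrier of many endothelia. Each library held normalised read counts for 30899 genes, of which 814 were listed at 0 in all 7 libraries. The normalised counts summed to 11855652, 13441728 and 13406183 in wild-type libraries 1 to 3 and to 15731074, 14774184, 14592369 and 15178656 in libraries 1 to 4 of the other group. From the spacing of low values, the reads behind these totals were estimated at 14736944 to 18020310 in wild type and 11260176 to 14156876 in the other group. The labels do not state that each library came from its own animal, so p-values measure only the spread between these libraries. No 2 libraries of a group held identical values.

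The series compares the genotypes to ask how loss of endothelial GLUT1 affects metabolic balance in muscle, with muscle macrophages named in its title. Slc2a1, the deleted gene, was not lower in the libraries labelled knockout. Its normalised counts were 1032, 1083 and 1266 in wild type and 952.6, 1435, 824.2 and 1087 in the libraries labelled knockout. The means were 1127 ± 123 (SD, n = 3) and 1075 ± 263 (SD, n = 4), a log2 fold change of -0.09 (SE 0.18, 95% interval -0.47 to 0.28, adjusted p = 0.738, two-sided exact permutation p = 0.743). A fall of Slc2a1 to under 0.722 of the wild-type level lies outside that interval. The sign of the Slc2a1 difference changed in 3 of 24 alternative settings. Which exons were deleted is not given in the sources used here. Because of this result, the second group is called the knockout-labelled libraries, and every direction given for it rests on the labels alone.

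**Figure D1:**
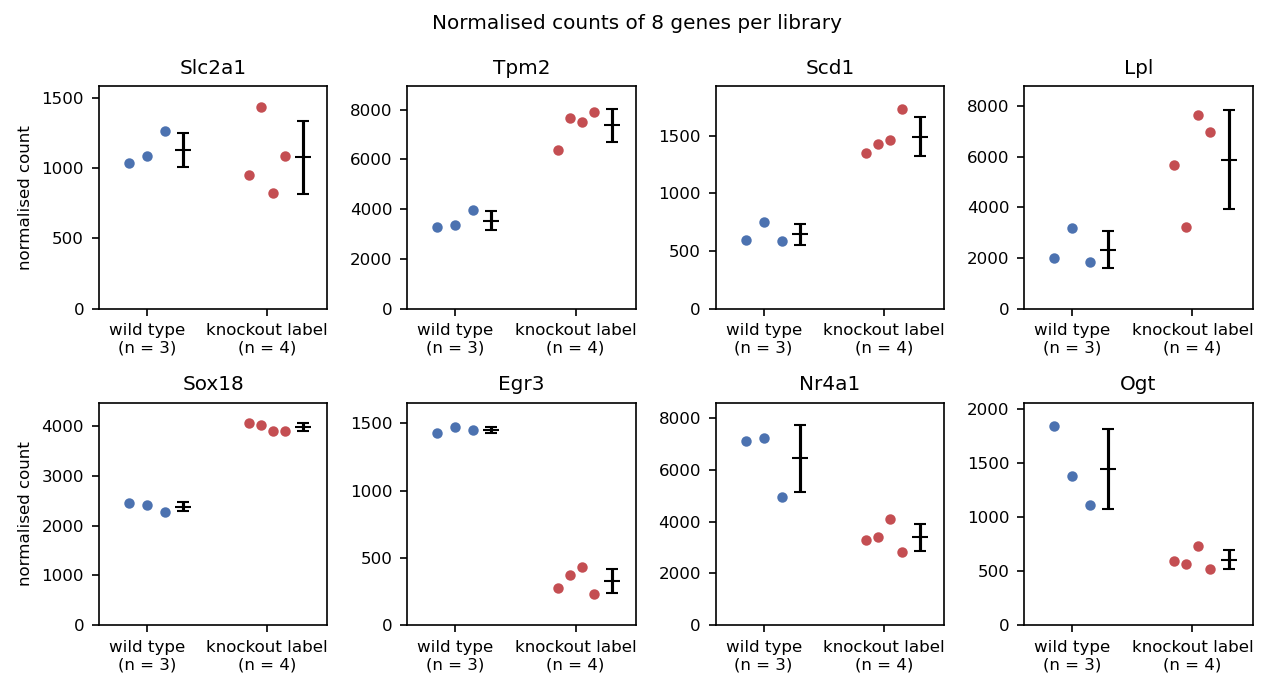
Normalised counts (y axes, from 0) of Slc2a1 and 7 changed genes in each library, as points for wild type (n = 3) and the knockout label (n = 4), with group mean and SD as bars. Slc2a1 values overlap between groups, with means of 1127 and 1075, whereas the values of Egr3 (1451 against 326) and Sox18 (2384 against 3979) do not.

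Of 16931 genes tested, 1949 changed, 1013 higher and 936 lower in the knockout-labelled libraries. The genes with the smallest p among the rises included Tpm2, a tropomyosin, which rose from 3525 ± 377 (SD, n = 3) to 7363 ± 678 (SD, n = 4), a log2 fold change of 1.06 (SE 0.13, adjusted p = 0.00156). Scd1, which desaturates long-chain fatty acids, rose from 644 ± 90.8 to 1492 ± 166 (log2 fold change 1.21, SE 0.14). Abcg1, a cholesterol exporter, rose by 1.06 (SE 0.14), Ly6c1 by 1.09 (SE 0.14) and Acta2, smooth muscle actin, by 0.97 (SE 0.13). Egr3, an immediate early transcription factor, fell from 1451 ± 19.5 to 326 ± 90.9, with a log2 fold change of -2.19 (SE 0.20, adjusted p = 0.00038). Also lower were Iqcn (-2.02, SE 0.23), the nuclear long noncoding RNA Neat1 (-1.82, SE 0.21), Fam71a (-1.93, SE 0.24) and the stress-responsive kinase Plk3 (-1.43, SE 0.18).

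Among changed genes with a mean of at least 50 and no overlap between groups, the largest rises belonged to the histone gene H3c2 (log2 fold change 1.98, SE 0.40), the mitochondrial adenylate kinase Ak4 (1.85, SE 0.43), the smooth muscle calponin Cnn1 (1.81, SE 0.22) and Ank1, an ankyrin (1.80, SE 0.32). Timp4, an inhibitor of matrix metalloproteinases, rose from 1388 ± 626 to 4520 ± 1417 (log2 fold change 1.72, SE 0.28). Prostacyclin synthase Ptgis rose by 1.71 (SE 0.37), the lysozyme gene Lyz2 by 1.67 (SE 0.28) and Metrn by 1.65 (SE 0.37). The largest falls among such genes were in genes of low or moderate level. Apol8 fell from 123 ± 10.5 to 14.6 ± 16.2 (log2 fold change -3.59, SE 0.67), and the fucosyltransferase gene Fut2 fell from 340.2 ± 59.8 to 55.1 ± 19.5 (log2 fold change -2.68, SE 0.32). Syn3 (-2.67, SE 0.45), Psg25 (-2.68, SE 0.67), Mamdc4 (-2.46, SE 0.51), the antisense transcript Kdm6bos (-2.45, SE 0.46), the leukotriene receptor gene Ltb4r1 (-2.43, SE 0.41) and Ifitm5 (-2.34, SE 0.58) were also lower. Each changed gene named in these 2 paragraphs had all 4 knockout-labelled values on one side of all 3 wild-type values, as the rule for naming required. Over all tested genes this held for 4871, or 28.8%, against 5.71% by chance.

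Rises and falls differed in level and kind of gene. Of the 936 lower genes, 566 had a mean under 100 and 47.2% were not listed as protein coding. Of the 1013 higher genes, 958 had a mean of at least 100 and 6.61% were not listed as protein coding. These shares count genes not matched to the annotation, 26 lower and 31 higher, whose kind is thus unknown here. At least 2-fold changes numbered 841, with 120 higher and 721 lower. With the libraries scaled to equal totals, which moved the median log2 fold change of all genes from 0.02 to -0.21, 228 genes were higher and 1645 lower, so the balance of directions depends on the scaling. The count of changed genes was 38 without wild-type library 1, 1057 without wild-type library 2, 601 without knockout-labelled library 1, 639 without knockout-labelled library 4 and 17 in limma without a mean-variance trend.

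**Figure D2:**
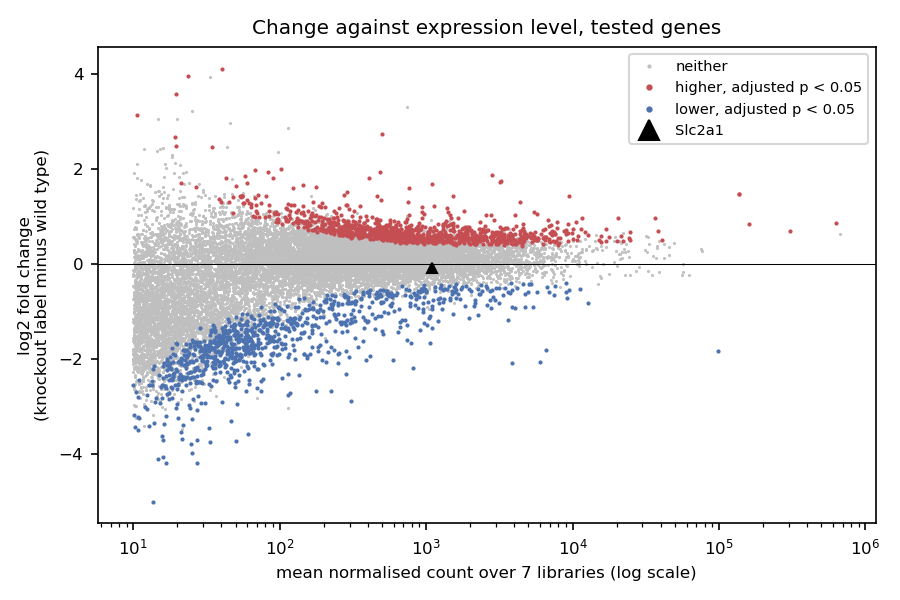
Log2 fold change, knockout label minus wild type (y axis), against the mean normalised count over 7 libraries (x axis, log scale) for the 16931 tested genes, with changed genes in colour and Slc2a1 as a triangle. Of the 936 lower genes, 566 lie at a mean under 100, against 55 of the 1013 higher genes.

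The libraries of the groups also differed in composition. Genes listed at 0 numbered 2794 to 6551 in wild type and 7301 to 9306 in the knockout-labelled libraries. The nuclear RNA Malat1, chosen after its values were seen, took 1.32% ± 0.603 (SD, n = 3) of the total in wild type and 0.311% ± 0.117 (SD, n = 4) in the knockout-labelled libraries. Olfactory and vomeronasal receptor genes, which few tissues other than sensory epithelia express, took 0.162% ± 0.0795 and 0.0534% ± 0.0129. Transcripts that collect ribosomal RNA reads took 9.88% and 14.1%, and the signal recognition particle RNA genes Rn7s1 and Rn7s2, which held identical values, took 1.03% and 2.49%. Of 9 library measures 8 separated the groups fully, each with an exact permutation p = 0.0286 (two-sided, adjusted p = 0.0321), the smallest p that 35 splits allow. The measures overlap, as they hold the receptor genes both by share and by mean, and they include the library totals and estimated reads. The receptor, ribosomal RNA, Malat1 and Rn7s measures were not part of the plan fixed before the data were examined. The count of 8 and its p-values may thus owe in part to that choice. The share of mitochondrially encoded mRNA was 1.06% and 1.29% (exact permutation p = 0.143). Among protein-coding genes with a mean of at least 100, the median log2 fold change was 0.63 for 126 genes with under 1000 exonic bases and 0.47 for 722 genes with 1000 to 2000, but 0.00 for 2117 genes with 8000 or more. With the receptor genes' mean log2 value as a covariate, limma called 0 genes, with 742 at an unadjusted p under 0.05. That value was 2.12 to 3.20 in wild type and 1.36 to 1.73 in the knockout-labelled libraries. It thus separates the groups but also varies within wild type.

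**Figure D3:**
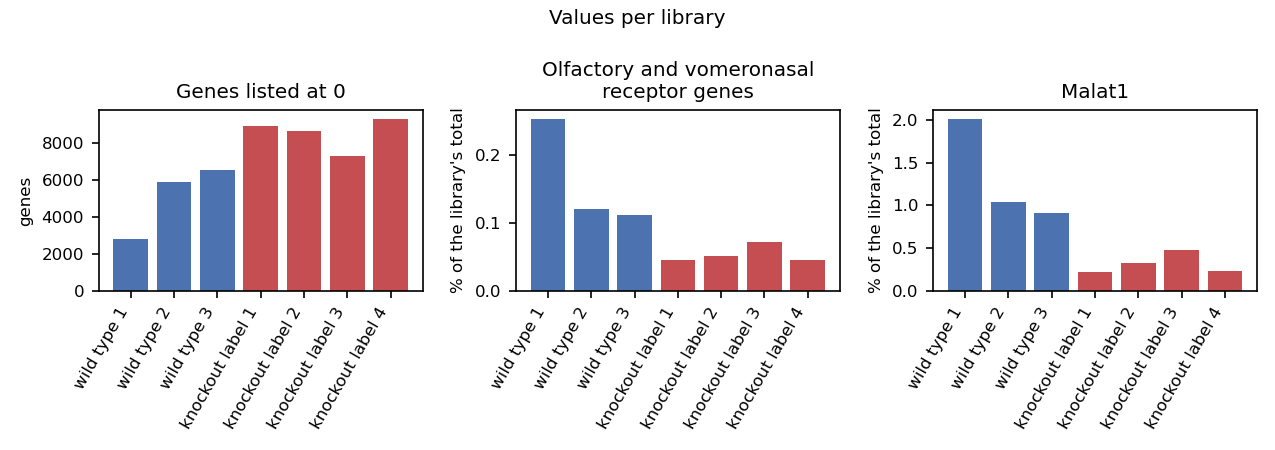
Genes listed at 0 (number), and the shares of olfactory and vomeronasal receptor genes and of Malat1 (percent of the library's total), as 1 bar per library from 0. Wild-type libraries hold 2794 to 6551 genes at 0 and the knockout-labelled libraries 7301 to 9306.

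Of 45 gene lists fixed before the data were examined, 43 could be tested and 22 were called, 21 higher and 1 lower. With an estimated correlation between genes 0 lists were called by camera (lowest adjusted p = 0.399), while the rotation test fry called 11, of which the hexosamine list (lower, adjusted p = 0.0165) was not among the 22. The medians of the 21 lists called higher stayed above 0 with equal totals, from 0.02 for the angiocrine list to 1.53 for the erythroid list. With the receptor covariate 6 of these medians were below 0, those of the pan-endothelial (-0.071), fatty acid uptake (-0.070), fatty acid oxidation (-0.034), capillary (-0.025), mitochondrially encoded (-0.0089) and fibroadipogenic progenitor (-0.0058) lists. Against random lists matched on mean expression 9 of the 22 kept their call, namely oxidative phosphorylation, capillary, fatty acid uptake, immediate early, Schwann cell, satellite cell, erythroid, fibroadipogenic progenitor and tenocyte. With exonic length matched too, on the members that allowed it, 6 of the 22 did. Of the 9 lists just named, the capillary, fatty acid uptake and tenocyte calls ended. The mitochondrially encoded list had 0 such members and was not compared. Random lists do not take up the spread between libraries. The mean over members overlapped between groups for the capillary and fibroadipogenic progenitor lists (exact permutation p = 0.114). It also did for the fatty acid uptake, erythroid and tenocyte lists (exact permutation p = 0.0857). Matching also called lists outside the 22. On mean expression these were the macrophage (adjusted p = 0.00752) and proliferation (adjusted p = 0.022) lists, above their matched lists, and on mean and length the Notch and shear (adjusted p = 0.0114), NF-kB and lymphatic (both adjusted p = 0.0448) lists, below theirs. With no filter on low values 9 more lists were called higher, those of arterial, venous, proliferation, macrophage, class I, interferon, integrated stress, cholesterol synthesis and serine genes. The medians of the lists are log2 fold changes, knockout label minus wild type.

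The 3 lists of mitochondrial energy metabolism were called higher, though none was with an estimated correlation. Of 27 nuclear genes of oxidative phosphorylation 15 rose, 0 fell and 12 did neither (23 rose adjusted over the list alone), with all 27 estimates above 0. Nuclear oxidative phosphorylation genes had a median of 0.57 (adjusted p = 2.35e-10, and adjusted p = 0.399 with an estimated correlation). The complex I subunit genes Ndufb8 (266 ± 60.9 to 496 ± 52.3, log2 fold change 0.92, SE 0.19), Ndufb10 (0.60, SE 0.14) and Ndufv2 (0.76, SE 0.18) and the cytochrome c oxidase subunit gene Cox4i1 (0.82, SE 0.17) were among them. Of 13 mitochondrially encoded mRNAs 7 rose and 6 did neither (13 rose adjusted over the list alone), including mt-Co3 (0.88, SE 0.21), mt-Nd3 (1.10, SE 0.27), mt-Atp8 (0.79, SE 0.17) and mt-Atp6 (0.51, SE 0.14). Mitochondrially encoded genes had a median of 0.57 (adjusted p = 3.83e-06, and adjusted p = 0.399 with an estimated correlation). The mitochondrially encoded call ended against lists matched on mean (adjusted p = 0.0654). Of 20 tricarboxylic acid cycle genes 6 rose and 14 did neither (9 rose adjusted over the list alone), with Sdhc at 0.78 (SE 0.14), Mdh2 at 0.70 (SE 0.15), Idh3a at 0.73 (SE 0.17) and Fh1 at 0.68 (SE 0.17). Tricarboxylic acid cycle genes had a median of 0.35 (adjusted p = 7.48e-05, and adjusted p = 0.399 with an estimated correlation). The tricarboxylic acid cycle call ended against lists matched on mean (adjusted p = 0.0965) and on mean and length (adjusted p = 0.263). In the same libraries shorter transcripts stood higher than longer ones, and 6 of 10 marker lists of other cell types were called higher (0 with an estimated correlation). With the length trend of expressed genes removed, the median was 0.17 for the oxidative phosphorylation list, which was still called, and 0.03 for the mitochondrially encoded list, whose call ended (adjusted p = 0.360 in limma camera).

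Some genes of fatty acid handling rose. In the same libraries the adipocyte marker Cfd was higher (mean normalised counts of 1.87 and 40.2, log2 fold change 3.95, SE 0.99, groups overlapping). Cfd was the 1 changed gene of the 2 adipocyte markers, of 6 fixed, that passed the filter on the mean. Of 15 uptake and storage genes 5 rose, 1 fell and 9 did neither (8 rose and 1 fell adjusted over the list alone). Fatty acid uptake genes had a median of 0.49 (adjusted p = 0.00683, and adjusted p = 0.399 with an estimated correlation). The fatty acid uptake call held against lists matched on mean (adjusted p = 0.0266) and ended on mean and length (adjusted p = 0.113). Lipoprotein lipase Lpl rose from 2334 ± 735 to 5878 ± 1959.7 (log2 fold change 1.30, SE 0.26), its endothelial anchor Gpihbp1 by 1.12 (SE 0.30, groups overlapping), the fatty acid binding protein gene Fabp5 by 0.76 (SE 0.19) and the nuclear receptor gene Pparg by 0.92 (SE 0.24). Dgat1, which makes triglyceride, fell by 1.11 (SE 0.25). The fatty acid translocase gene Cd36 was at 15629 ± 4256 and 21589 ± 3486 (log2 fold change 0.49, SE 0.19, adjusted p = 0.0938). Of 18 fatty acid oxidation genes 5 rose and 13 did neither (7 rose adjusted over the list alone), including Acadm (0.60, SE 0.17), Hadhb (0.62, SE 0.18), Hadh (0.54, SE 0.16) and Pdk4 (0.81, SE 0.25), which restrains pyruvate dehydrogenase. Fatty acid oxidation genes had a median of 0.35 (adjusted p = 0.00116, and adjusted p = 0.399 with an estimated correlation). The fatty acid oxidation call ended against lists matched on mean (adjusted p = 0.0946) and on mean and length (adjusted p = 0.343). Of 19 cholesterol synthesis genes 1 rose (1 adjusted over the list alone), and the list was not called (median 0.18, adjusted p = 0.314).

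The glycolytic and pentose phosphate lists were called higher, though neither was with an estimated correlation. Of 16 glycolytic genes 5 rose, 1 fell and 10 did neither (7 rose and 2 fell adjusted over the list alone). Glycolytic genes had a median of 0.38 (adjusted p = 0.00307, and adjusted p = 0.399 with an estimated correlation). The glycolytic call ended against lists matched on mean (adjusted p = 0.0654) and on mean and length (adjusted p = 0.343). Pgk1 (0.69, SE 0.16), Gapdh (0.58, SE 0.13), Ldhb (0.72, SE 0.17) and Aldoa (0.58, SE 0.14) rose, whereas the hexokinase genes Hk1 (0.09, SE 0.12, adjusted p = 0.625) and Hk2 (0.70, SE 0.61, adjusted p = 0.440) and the glycolytic activator gene Pfkfb3 (-0.50, SE 0.17, adjusted p = 0.065) did not pass. Of 8 pentose phosphate genes 2 rose, Taldo1 (0.62, SE 0.15) and Tkt (0.46, SE 0.13), and 6 did neither (3 rose adjusted over the list alone). Pentose phosphate genes had a median of 0.37 (adjusted p = 0.00683, and adjusted p = 0.399 with an estimated correlation). The pentose phosphate call ended against lists matched on mean (adjusted p = 0.225) and on mean and length (adjusted p = 0.292). Among 12 other sugar and lactate transporters 0 changed (0 adjusted over the list alone; median 0.22, adjusted p = 0.538), with Slc2a3 at 0.77 (SE 0.43, adjusted p = 0.228), Slc16a1 at 0.39 (SE 0.29, adjusted p = 0.356) and Slc2a4 at 0.68 (adjusted p = 0.0548). Of 7 genes of hexosamine synthesis and O-GlcNAc cycling 0 rose and 2 fell (2 fell adjusted over the list alone; median -0.21, adjusted p = 0.0999), both enzymes of the cycle itself, Ogt (1446 ± 371 to 604 ± 89.2, log2 fold change -1.24, SE 0.18) and Oga (-0.51, SE 0.12). The hexosamine list was called lower in 2 of 22 settings, by fry (adjusted p = 0.0165) and with quantile normalization (adjusted p = 0.0371), and adjusted p over all reached 0.438. The glucose-sensing list of 5 genes had 0 changed (0 adjusted over the list alone; median -0.16, adjusted p = 0.435), and Txnip, a glucose-responsive gene, stood at 15885 ± 1136 and 16175 ± 3334 (log2 fold change 0.00, SE 0.16, adjusted p = 0.989). Of 11 glutamine and aspartate genes 1 fell, the amino acid transporter gene Slc38a2 (-0.56, SE 0.15), also adjusted over the list alone (median 0.27, adjusted p = 0.707), and of 10 serine and one-carbon genes 0 changed (0 adjusted over the list alone; median 0.31, adjusted p = 0.190). Of 12 insulin signalling genes 0 changed (0 adjusted over the list alone; median 0.11, adjusted p = 0.398).

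The pan-endothelial and capillary lists were called higher, though neither was with an estimated correlation, in the libraries in which the marker lists of Schwann cells (4 of 5 genes higher) and fibroadipogenic progenitors (4 of 14 genes higher) were too. Of 20 pan-endothelial genes 5 rose, 1 fell and 14 did neither (9 rose and 1 fell adjusted over the list alone). Pan-endothelial genes had a median of 0.32 (adjusted p = 0.000182, and adjusted p = 0.399 with an estimated correlation). The pan-endothelial call ended against lists matched on mean expression (adjusted p = 0.575). For the 16 members that could be matched on length too, the median was 0.36 and that of the random lists 0.36 (adjusted p = 0.966). Sox18, a vascular transcription factor, rose from 2384 ± 94.2 to 3979 ± 78.7 (log2 fold change 0.74, SE 0.11), Mmrn2 rose by 0.48 (SE 0.14) and Ramp2 by 0.61 (SE 0.14), while Egfl7 fell by 0.47 (SE 0.13). Pecam1 (0.25, SE 0.14, adjusted p = 0.236), Cdh5 (0.42, SE 0.16, adjusted p = 0.0969), Kdr (0.48, SE 0.23, adjusted p = 0.161) and Nos3 (-0.24, SE 0.12, adjusted p = 0.172) did not pass. Of 14 capillary genes 4 rose and 10 did neither (10 rose adjusted over the list alone), among them Timp4, the carbonic anhydrase gene Car4 (1.34, SE 0.34) and the water channel gene Aqp1 (0.70, SE 0.21); for Car4 and Aqp1 the groups overlapped. Capillary genes had a median of 0.64 (adjusted p = 7.48e-05, and adjusted p = 0.408 with an estimated correlation). The capillary call held against lists matched on mean (adjusted p = 0.00143) and ended on mean and length (adjusted p = 0.0788). Of 16 arterial genes 2 rose, the gap junction gene Gja4 (0.78, SE 0.15) and Stmn2 (0.62, SE 0.16), and the list was not called (2 rose adjusted over the list alone; median 0.12, adjusted p = 0.0873). The arterial list was called higher in 5 of 22 settings (adjusted p of 0.00266 to 0.990 over all), among them without knockout-labelled library 3 (adjusted p = 0.0383). The 10 venous genes (median 0.16, adjusted p = 0.228) and 6 lymphatic genes (median -0.11, adjusted p = 0.839) held 0 changed genes, also adjusted over the list alone. Of 18 tip cell genes 2 rose and 1 fell (the same counts adjusted over the list alone), namely Cxcr4 (1.11, SE 0.26), Pdgfb (0.63, SE 0.17) and Plaur (-0.82, SE 0.20). Tip cell genes had a median of 0.36 (adjusted p = 0.00899, and adjusted p = 0.416 with an estimated correlation). The tip cell call ended against lists matched on mean (adjusted p = 0.128) and on mean and length (adjusted p = 0.292). Of 14 basement membrane genes 2 rose, Sparc (0.97, SE 0.20) and perlecan gene Hspg2 (0.55, SE 0.16, groups overlapping), and 12 did neither (6 rose adjusted over the list alone). Basement membrane genes had a median of 0.41 (adjusted p = 0.00133, and adjusted p = 0.399 with an estimated correlation). The basement membrane call ended against lists matched on mean (adjusted p = 0.274) and on mean and length (adjusted p = 0.0555). Of 13 Notch and shear response genes 2 fell, Klf4 (11177 ± 1112 to 7452 ± 751, log2 fold change -0.58, SE 0.13) and Notch1 (-0.40, SE 0.11), and the list was not called (2 fell adjusted over the list alone; median -0.10, adjusted p = 0.398). It was called lower in 3 of 22 settings (adjusted p of 0.00938 to 0.982 over all), among them lists matched on mean and length, whose median was 0.27. Of 25 proliferation genes 3 rose, Mcm2 (0.91, SE 0.22), Mki67 (0.85, SE 0.23) and Ccna2 (1.38, SE 0.42), also adjusted over the list alone, without a list call (median 0.31, adjusted p = 0.0813). That list was called higher in 10 of 22 settings (adjusted p of 0.00069 to 0.408 over all), among them without wild-type library 1 (adjusted p = 0.0104), without knockout-labelled library 3 (adjusted p = 0.0433) and against lists matched on mean, but not on mean and length (adjusted p = 0.343).

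Of 4 stress lists 3 were called higher, though none was with an estimated correlation. The list of 21 immediate early and dissociation-induced genes was the 1 list called lower (median -0.23, adjusted p = 0.00107; adjusted p = 0.408 with an estimated correlation). In it 3 genes fell and 18 did neither, with the same 3 adjusted over the list alone: Egr3, the orphan receptor gene Nr4a1 (6446 ± 1284 to 3400.4 ± 529, log2 fold change -0.91, SE 0.16) and the chaperone gene Hsp90aa1 (13777 ± 2866 to 9486 ± 1029, log2 fold change -0.52, SE 0.15). Of 16 genes of the unfolded protein response in the endoplasmic reticulum 4 rose, the chaperone Hsp90b1 (0.41, SE 0.12) and the disulfide isomerases Pdia3 (0.56, SE 0.13), Pdia4 (0.44, SE 0.13) and Pdia6 (0.45, SE 0.13), and 12 did neither (6 rose adjusted over the list alone). Unfolded protein genes had a median of 0.37 (adjusted p = 0.00046, and adjusted p = 0.399 with an estimated correlation). The unfolded protein call ended against lists matched on mean (adjusted p = 0.0656) and on mean and length (adjusted p = 0.559). Of 20 hypoxia genes 5 rose, 1 fell and 14 did neither (11 rose and 2 fell adjusted over the list alone), including Ankrd37 (1.60, SE 0.35) and the oxygen sensor gene Egln1 (0.54, SE 0.13), while the histone demethylase gene Kdm3a fell by 0.88 (SE 0.14). Hypoxia genes had a median of 0.34 (adjusted p = 0.0201, and adjusted p = 0.399 with an estimated correlation). The hypoxia call ended against lists matched on mean (adjusted p = 0.121) and on mean and length (adjusted p = 0.292). Of 15 antioxidant genes 2 rose, Gstm1 (0.86, SE 0.18) and the glutathione synthesis gene Gclm (0.80, SE 0.19; 4 rose adjusted over the list alone). Antioxidant genes had a median of 0.34 (adjusted p = 0.00683, and adjusted p = 0.399 with an estimated correlation). The antioxidant call ended against lists matched on mean (adjusted p = 0.121) and on mean and length (adjusted p = 0.738). Of 23 integrated stress response genes Vldlr rose (1.46, SE 0.27) and Chac1 fell (-1.22, SE 0.36), the same counts adjusted over the list alone, without a list call (median 0.21, adjusted p = 0.230).

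Some immune genes and genes of signals to macrophages changed, in libraries in which Lyz2 rose and 6 of 10 marker lists of other cell types were called higher (0 with an estimated correlation). Of 22 angiocrine genes 2 rose, the morphogen gene Bmp6 (1569.7 ± 341 to 2896 ± 413, log2 fold change 0.89, SE 0.16) and the galectin gene Lgals3 (0.99, SE 0.23), and 20 did neither (3 rose adjusted over the list alone). Angiocrine genes had a median of 0.25 (adjusted p = 0.00958, and adjusted p = 0.399 with an estimated correlation). The angiocrine call ended against lists matched on mean (adjusted p = 0.246) and on mean and length (adjusted p = 0.694). Spp1, which encodes osteopontin, was at 179.9 ± 43.2 and 249 ± 48.3 (log2 fold change 0.48, SE 0.23, adjusted p = 0.166), and the macrophage growth factor gene Csf1 at a log2 fold change of 0.18 (SE 0.17, adjusted p = 0.479); neither passed. Of 9 genes of class I antigen presentation 2 rose, B2m (0.57, SE 0.12) and Psmb8 (0.54, SE 0.13), and their activator Nlrc5 fell by 1.09 (SE 0.23; 5 rose and 1 fell adjusted over the list alone; median 0.30, adjusted p = 0.0569). The class I list was called higher in 6 of 22 settings (adjusted p of 0.00412 to 0.565 over all), among them without wild-type library 1 or 3 or knockout-labelled library 4 (adjusted p = 0.0243, 0.0431 and 0.0386). Of 7 class II genes the transactivator gene Ciita fell (-1.92, SE 0.57), also adjusted over the list alone (median -0.23, adjusted p = 0.357). Of 22 interferon response genes 3 rose and 2 fell (6 rose and 2 fell adjusted over the list alone; median 0.25, adjusted p = 0.110), with Irf7 (0.64, SE 0.16), Ifit3 (0.54, SE 0.13) and Gbp2 (0.56, SE 0.14) higher and Stat2 (-1.01, SE 0.17) lower. The interferon list was called higher in 2 of 22 settings (adjusted p of 0.00293 to 0.560 over all), 1 of them without knockout-labelled library 2 (adjusted p = 0.0454). Of 16 inflammatory and adhesion genes under NF-kB 0 changed (0 adjusted over the list alone; median -0.04, adjusted p = 0.969), and the list was called lower only against lists matched on mean and length.

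Marker lists of other cell types were among those called higher, in the same libraries in which the metabolic, endothelial, stress and angiocrine lists were, and likewise not with an estimated correlation. Of 5 Schwann cell genes 4 rose (5 adjusted over the list alone), with the myelin gene Mbp at 4469 ± 709 and 8549 ± 1714 (log2 fold change 0.93, SE 0.16) and Ncmap at 0.76 (SE 0.17). Schwann cell genes had a median of 0.76 (adjusted p = 0.000154, and adjusted p = 0.399 with an estimated correlation). Of 8 satellite cell genes 4 rose (7 adjusted over the list alone), namely Des (0.60, SE 0.12), Cdh15 (1.16, SE 0.25), Pax7 (0.91, SE 0.21) and Myod1 (normalised counts of 1.78 to 32.9). Satellite cell genes had a median of 0.94 (adjusted p = 0.000182, and adjusted p = 0.399 with an estimated correlation). All 5 erythroid genes rose (5 adjusted over the list alone), with Alas2 at 1.53 (SE 0.33) and the haemoglobin gene Hba-a2, whose reads a close paralogue shares, at 1338 ± 764 and 4639.8 ± 2568. For Hba-a1, Hba-a2, Hbb-bs and Hbb-bt the groups overlapped. Erythroid genes had a median of 1.75 (adjusted p = 0.000287, and adjusted p = 0.399 with an estimated correlation). Of 12 pericyte and smooth muscle genes 5 rose (6 adjusted over the list alone), including Acta2, Cnn1, Myl9 (1.02, SE 0.15) and Myh11 (0.68, SE 0.15), while Rgs5 stood at -0.02 (adjusted p = 0.962). Pericyte genes had a median of 0.33 (adjusted p = 0.00108, and adjusted p = 0.399 with an estimated correlation). The pericyte call ended against lists matched on mean (adjusted p = 0.316) and on mean and length (adjusted p = 0.573). Of 14 fibroadipogenic progenitor genes 4 rose and 10 did neither (5 rose adjusted over the list alone), with rises in Gsn (0.93, SE 0.14), Col3a1 (1.03, SE 0.20), Col1a2 (0.68, SE 0.14) and Col1a1 (0.76, SE 0.21). Fibroadipogenic progenitor genes had a median of 0.70 (adjusted p = 0.00157, and adjusted p = 0.408 with an estimated correlation). Of 5 tenocyte genes Thbs4 (1.00, SE 0.25) and Tnmd (1.31, SE 0.40) rose (2 adjusted over the list alone), and the call ended without wild-type library 1 or 2 or knockout-labelled library 1 or 4 (adjusted p = 0.0587, 0.112, 0.0685 and 0.0607 in limma camera). Tenocyte genes had a median of 0.69 (adjusted p = 0.0465, and adjusted p = 0.399 with an estimated correlation). The tenocyte call held against lists matched on mean (adjusted p = 0.0224) and ended on mean and length (adjusted p = 0.343).

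Of 13 macrophage genes 1 rose, Lyz2 (1 rose and 2 fell adjusted over the list alone), and the list was not called (median 0.50, adjusted p = 0.398). It was called higher in 2 of 21 settings (adjusted p of 0.00752 to 0.753 over all), with no filter on low values and against lists matched on mean, whose median was -0.36. The 20 muscle fibre genes held 0 changed genes (0 adjusted over the list alone; median 0.22, adjusted p = 0.538), and of 3 neutrophil genes Cxcr2 fell (normalised counts of 34.7 to 1.41), also adjusted over the list alone, with a list median of 0.33 but a mean of -0.91 and a test direction downward (adjusted p = 0.529). The lymphocyte and adipocyte lists were not tested, as only 2 of 12 and 2 of 6 genes passed the filter on the mean. In each 1 gene changed, Cd3d lower (-1.49, SE 0.37) and Cfd higher (3.95, SE 0.99, groups overlapping). The 5 sex-linked genes held 0 changed genes (0 adjusted over the list alone; median -0.14, adjusted p = 0.545).

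**Figure D4:**
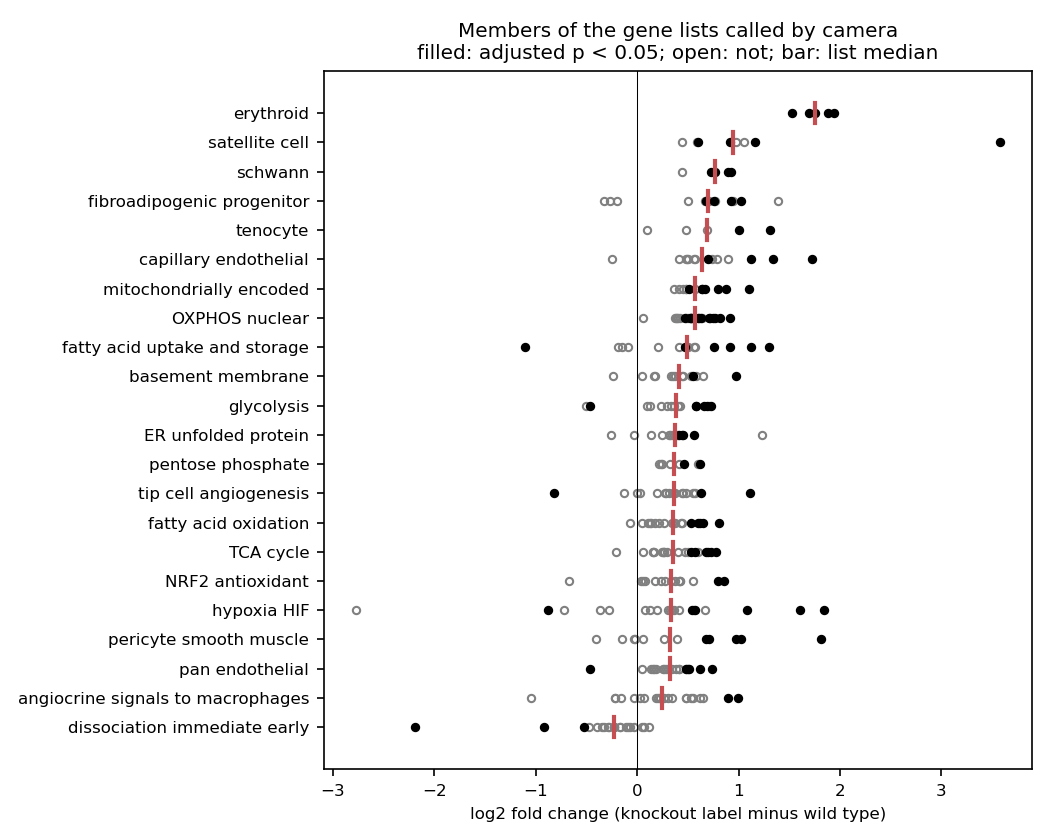
Log2 fold change, knockout label minus wild type (x axis), of each tested member of the 22 lists called by camera (y axis), filled where the gene passed an adjusted p of 0.05 and open where it did not, with the list median as a bar. Medians of the lists called higher run from 0.25 (angiocrine) to 1.75 (erythroid), and the list called lower, immediate early genes, has a median of -0.23.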

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

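Chosen only after the result was seen were the tests of swapped labels, undeleted exons, RNA of other cells and sequencing depth, and both tests against lists matched on exonic length.

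Slc2a1 was not lower in the knockout-labelled libraries. Single finished libraries swapped between the groups are argued against, since 7 of 7 libraries correlated better on average with their own group. Labels exchanged for the groups as a whole would leave that so, and neither this nor a swap with an outside sample was tested. Single pairs overlapped: the highest correlation between groups was 0.957, and the lowest was 0.954 within wild type and 0.952 within the knockout label. The correlations may reflect the difference in composition between the groups. They therefore cannot show whether a library prepared with its group had the genotype of its label. Reads from exons left in place may still count for the gene: the 95% interval reaches down to a log2 fold change of -0.47, and values per exon are not analysed here. RNA of other cells could also supply Slc2a1 reads, and this stays open. After bead isolation 6 of 10 lists of other cell types were called higher (Mbp at 8549 and Myh11 at 29627 normalised counts), though 0 were with an estimated correlation. The pan-endothelial mean was higher by 0.31 (SE 0.10) over all 20 members. The 16 members that could be matched on mean expression and length did not separate from their matched genes (excess 0.02, exact permutation p = 0.457). That the transporter's mRNA is not reduced in these cells was not tested apart from these.

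Genes lower in the knockout-labelled libraries were often low or noncoding. A uniform background over silent genes is a candidate explanation for those with a mean under 100, where subtracting the receptor level ended 67.8% of 566 calls. It is argued against for most of the 98 with a mean of at least 1000, where subtraction ended 10.2%. The contrast was partly fixed in advance, as more was subtracted in wild type and low values lose the largest share. Subtraction left 14867 genes tested, against 16931, so calls on low genes could also end by leaving the test. More nuclear RNA in the wild-type libraries may account for part. Only in sense-intronic transcripts do the values bear on telling it apart from a uniform background. The median log2 fold change was -1.39 in 92 tested sense-intronic transcripts and -1.42 in 296 tested receptor genes. Genes near the filter on the mean can pass it through high wild-type values alone. Over all 281 sense-intronic transcripts the level per kilobase was 15.5 to 20.8 in wild type and 10.8 to 13.4 in the knockout-labelled libraries. Over all 1143 receptor genes it was 3.04 to 6.08 and 1.39 to 2.13. Wild type stood higher per kilobase by 5.89 in sense-intronic transcripts and by 2.51 in receptor genes. A background equal per kilobase in both classes would give like differences. It is thus argued against as the whole of the sense-intronic fall. Whether nuclear RNA makes up the rest was not tested, and for lower genes as a whole the 2 were not told apart. Depth of sequencing is argued against, since it leaves shares alike and the receptor share was 3.03 times as high in wild type. The genotype stays open as a cause, untested, because these measures follow the groups.

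The rise of the 27 nuclear oxidative phosphorylation genes is argued not to come from abundance, as none of 10000 lists matched on mean expression had a median as high (0.010% when 1 is added to both counts, the smallest value the draws can give), nor from muscle fibre RNA, whose list rose in sum by 0.000624 of the oxidative phosphorylation sum. A length trend over all genes is argued against, since removing it left a median of 0.77, against a shift of 0.19 in all genes, whereas removing the trend of expressed genes left 0.17, against a shift of -0.11, with the list still called (adjusted p = 2.5e-05). Shorter transcripts rising against longer ones may account for part of the rise. Lists matched on mean and length had a median of 0.39, against 0.55 for the 25 of 27 members that could be matched. That trend is argued against as the whole, as these members exceeded matched genes by 0.20 more in the knockout-labelled libraries (two-sided exact permutation p = 0.0286, the smallest possible, and the lowest adjusted p over 38 lists was 0.0987). RNA of other cells, 6 of whose lists were called higher (0 with an estimated correlation), and the genotype stay open.

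Chance division of the libraries is argued against for the 3 counts, which come from 1 fit. Only 1 of the 35 splits, the real one, gave as many changed genes (1949, highest other 184). The same held for higher genes (1013, highest other 168) and lower genes (936, highest other 16). With 35 splits the smallest exact permutation p is 0.0286, so chance is not excluded.

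In 11 of 167 quantities, where chance gives about 8.35, 1 of the 4 knockout-labelled libraries lay far from the other 3; the number given is its gap to the nearest as a share of the group's range. Library 2 was low for Timp4 (2413 against 4992 to 5441, 0.894), Bmp6 (2287 against 2997 to 3165, 0.832), Cd36 (16420 against 22650 to 23900, 0.857) and Slc16a1 (134.5 against 213.8 to 227.9, 0.879). Library 3 was low for Gja4 (the others at 1243 to 1290, 0.867), Mki67 (174.3 against 259.7 to 272.2, 0.895) and Comp (133.1 against 313.8 to 330.5, 0.943), and high for Mlx (339.4 against 241.8 to 251.6, 0.883). Library 4 was low for Psg25 (2.20 against 21.3 to 31.7, 0.835) and Idh3a (563.2 against 642.4 to 656.7, 0.856), and high for Acadm (1169 against 775.7 to 825.1, 0.850).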

How the results depend on the processing

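The receptor covariate, receptor subtraction, both length corrections and the matched random lists were chosen after the data were seen. The 1949 changed genes (1013 higher, 936 lower) moved beyond 1.5 times under these settings. A mean of at least 50 gave 563 lower genes, with fewer genes tested. Quantile normalization gave 1102 changed and 447 higher. Equal totals gave 228 higher and 1645 lower, as it shifts all genes down. Limma without trend gave 17 changed, 0 higher and 17 lower, with 4926 at an unadjusted p under 0.05. The muscle fibre covariate gave 933 (467 higher, 466 lower), and an adjusted p of 0.10 gave 3842 (1954 higher, 1888 lower) by its looser threshold. The receptor covariate gave 0 changed, 0 higher and 0 lower (742 at an unadjusted p under 0.05) and 5 lists. It separates the groups and also varies within wild type (2.12 to 3.20, against 1.36 to 1.73 in the knockout-labelled libraries). Whether calls ended through its overlap with the groups or through the composition it measures cannot be told. Receptor subtraction gave 478 lower, with 14867 genes tested. Removing the length trend of all genes gave 3282 changed and 2472 higher, and removing that of expressed genes gave 280 higher. Leaving out 1 library gave 38 to 1992 changed, 16 to 997 higher and 22 to 1127 lower. Without wild-type library 1, 16 of the 122 changed named genes stayed called. Without wild-type library 2 or 3 it was 88 and 103, so fewer libraries alone do not account for that loss. Wild-type library 1 had a receptor share of 0.254%, against 0.121% and 0.112% in wild-type libraries 2 and 3. Its Malat1 share was 2.01%, against 1.04% and 0.904%. In each of these settings 0 genes were called in the opposite direction. Other causes were not tested.

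With the replicate number as a block (the replicate block), 119 genes changed, 35 higher and 84 lower. Libraries of the same number correlated at -0.08, -0.05 and -0.12 across genes after group means were removed, and those of unlike number at -0.12 to 0.20. These values give no sign that the numbers pair libraries, but so few cannot exclude it. This paired setting removes degrees of freedom. It also leaves knockout-labelled library 4 without a wild-type partner, and leaving out that library alone gave 639 changed genes.

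Slc2a1 ranged from -0.43 to 0.09 over 24 settings (adjusted p 0.220 to 0.996), and turned positive with the macrophage covariate (0.045), with the length trend of all genes removed (0.091) and without knockout-labelled library 3 (0.023); leaving out 1 library gave -0.24 to 0.023. With the receptor covariate, signs turned for Aqp1 (-0.043), Fabp5 (-0.0093), Col1a1 (-0.17) and mt-Nd3 (-0.020), and with the length trend of expressed genes removed for mt-Atp8 (-0.044) and mt-Atp6 (-0.094); the cause was not tested. Lists called numbered 0 with an estimated correlation, 11 by fry (10 of the 22), 11 against lists matched on mean expression (9 of the 22) and 9 against lists matched on mean expression and length (6 of the 22). Of the 22, 17 kept their call with quantile normalization, 17 with receptor subtraction and 4 with the receptor covariate. With the length trend of all genes removed 20 did, and with that of expressed genes removed 18 did. Among named genes 2854 results kept their side of the threshold, 857 lost a call and 34 gained one; among lists the counts were 803, 101 and 36. Of those that kept their side, 79 uncalled results changed sign. Tests on whole reads were not run, and the depth of 11260176 to 18020310 estimated reads limits genes of low value.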

Other observations

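The classes of transcript and the single RNAs named here were chosen after their values were seen, as were the comparisons with matched genes. Rn7s1, RNA of the signal recognition particle, rose from 67191 ± 17096 (SD, n = 3) to 188675 ± 58784 (SD, n = 4), a log2 fold change of 1.47 (SE 0.24). Rmrp, RNA of a ribonuclease, rose by 1.44 (SE 0.27), Rpph1, RNA of ribonuclease P, by 0.97 (SE 0.21), Snord17 by 1.61 (SE 0.24) and Scarna10 by 1.21 (SE 0.23). Of 10 tested snoRNA genes 4 rose, 0 fell and 6 did neither (median 0.74). Malat1 fell from 166612 ± 62893 to 46436 ± 16214 (log2 fold change -1.84, SE 0.26).

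No class of transcript was tested for enrichment, and in each most genes did not pass. Of 592 long intergenic RNAs 9 rose and 87 fell (median -1.09), of 562 antisense transcripts 0 rose and 67 fell (median -0.98), and of 92 sense-intronic transcripts 0 rose and 16 fell. Among 13768 protein-coding genes 946 rose and 494 fell (median 0.11).

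Against genes matched on mean expression and length, 11 of 38 lists separated the groups fully in their mean (exact permutation p = 0.0286, the smallest possible; lowest adjusted p = 0.0987), 7 higher and 4 lower. The 4 of 8 satellite cell genes that could be matched exceeded matched genes by 0.69 more in the knockout-labelled libraries, and the tricarboxylic acid cycle list by 0.19 more. Against matched genes 15 of the 21 immediate early genes stood lower there by 0.75 in their mean, and the Notch and shear list by 0.29. The mean log2 fold changes of these 2 lists themselves, over all tested members, were -0.33 and -0.06. In the 16 of 20 pan-endothelial genes that could be matched the difference was 0.02 (exact permutation p = 0.457).

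The Y-linked gene Ddx3y lay between 1027 and 1166 in all 7 libraries. Xist stood at 67.7 in wild-type library 2 and at 0 to 5.73 in the others.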
